A study of Pyrococcus furiosus with 18 samples.

How the data were processed

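RNA of Pyrococcus furiosus was measured in 18 microarray samples with 2 channels each, per the labels. Each such sample is called an array here, although some appear to share a slide, as given below. Cells from 2 cultures were sampled at 10, 20, 30 and 60 min after elemental sulfur was added, and the 0 min RNA of the same culture was labelled with Alexa 647 and placed on every array as the second RNA. The RNA of the later time carried Alexa 488, 546 or 594. Each combination of culture and time was hybridized on 2 arrays, or 3 at 30 min. Repeat arrays were treated as technical, and the culture as the replicate (n = 2 per time). Samples were placed in groups by the time in their titles. A treatment label that gives 10 min for all samples was not used for this, because the titles give different times.

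Each array held 6576 spots in 24 print blocks, 3 spots for each of 2192 genes. The scanner files give a signal and a local background for both channels as intensity on a linear scale, per the file headers. The software that read the spots, any spot exclusion and any scaling are not given in the sources used here. In the deposited intensity columns the sample channel had been multiplied by 1 factor per array, as the values themselves show, and division by that factor gave back whole numbers (tolerance 0.05) in 100% of the spots of every array. Those recovered values were used. A spot with a signal of 1 in both channels was taken as excluded by whoever read the array: there were 40 to 177 per array, 1840 of 118368 in all, and they were left out. The files also hold a log2 ratio per spot, and a deposited value table gives log2 ratios per gene, which per the values are the mean of the 3 spots of the authors' log2 ratios of background-subtracted signals, sample over 0 min. That table is not centred, with medians from -0.383 to 0.300 over the arrays. Its columns for 2 of the 30 min arrays of culture 1 are exchanged relative to the scanner files, and were used as labelled. In the scanner file of 1 array of 30 min in culture 2 the gene names are not aligned with the spot positions, so genes were assigned by position, as in the other files, after which the correlation with the deposited ratios was 1.0 against 0.0218 before. Gene names and products are those of the files, whose annotation may be old. No genome was used here, so coordinates are not given.

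Background was corrected in limma 3.58.1 (R 4.3.3) with normexp and an offset of 50, and each array's log2 ratio of sample over 0 min was normalized by loess over all gene spots (span 0.3, 4 iterations). The mean of the 3 spots was taken per gene, and the arrays of 1 culture and time were averaged, which left 8 values per gene. A linear model with a term per time was fitted to them, with 4 residual and 2.77 prior degrees of freedom after the empirical Bayes step. Sharing 1 estimate of the spread among times was needed because 2 cultures alone leave 1 residual degree of freedom. Each time was tested against 0, two-sided, and 60 min against 10 min. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 0 min RNA was on every array of its culture, so the tests against 0 min have no separate spread for 0 min, and the comparisons share it. Ratios are relative to the centre of each array and cannot show a change common to all genes.

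Gene lists were fixed before the data were examined: soluble hydrogenase I and II, membrane-bound hydrogenase, the mbx cluster, sulfur response genes, hydrogenase maturation, ferredoxin NADP oxidoreductases, iron uptake and storage, oxidative stress, glycolysis and gluconeogenesis, 2-oxoacid ferredoxin oxidoreductases, acetyl-CoA synthetases, maltose and maltodextrin uptake and use, archaeal ATP synthase, branched-chain, tryptophan, aromatic, histidine, arginine and lysine, and methionine synthesis, glutamate and glutamine metabolism, and heat shock and stress. By product name there were ribosomal proteins, aminoacyl-tRNA synthetases, archaellum, RNA polymerase subunits and transposases. Lists for CRISPR-associated proteins and iron-sulfur cluster assembly found 0 members by product name and have no result. Some list names are broader than their members: the ribosomal list holds PF0209 and PF1682, which its name rule drew in, the histidine list a histidyl-tRNA synthetase, and the aromatic list PF1694 to PF1698 of other or unnamed products. Each list was tested with camera, which compares it with all other genes, at a preset inter-gene correlation of 0.01, two-sided, and adjusted over 135 tests (27 lists in 5 comparisons). With the correlation estimated from these 8 values camera passed 0 of the 135 tests, of which 26 had an unadjusted p under 0.05. The count adjusted over the list alone corrects for the members of that list. The lists for hydrogenases, mbx and sulfur came from prior knowledge that in part comes from the study of these same samples.

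Genes named in the text follow a rule fixed before the data were examined. For each time against 0 min these are the 5 highest and 5 lowest called genes with the same direction in both cultures, up to 4 called genes with the largest ratio from each list, and 10 genes named whatever their test (PF1186, PF2025, PF2026, PF0095, PF0894, PF1332, PF1434, PF1442, PF1453 and PF1909). For 60 min against 10 min they are the 5 highest and 5 lowest called genes. Others are said to be chosen after their values were seen.

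The pairing of cultures over time was checked by the correlation over genes of the cultures' deviations from their mean. It was 0.396 between 10 and 20 min, 0.429 between 10 and 30, 0.180 between 10 and 60, 0.727 between 20 and 30, 0.534 between 20 and 60 and 0.625 between 30 and 60 min. The same cultures were sampled over time, so culture numbers pair the samples, and part of these correlations comes from the shared 0 min RNA. A fit with culture as a block was computed as an alternative, because the main design had been fixed without it. Against 0 min, where values are already ratios within a culture, the block takes a culture's common shift out of the spread. Its calls there are less strict and do not measure how far the cultures agree. Alternatives tried were median centring, print-tip loess, no background correction, an offset of 16, leaving out the dimmest genes, keeping the excluded spots, the deposited value table, all 18 arrays with culture and time, hybridization day or slide as a random block, a sample dye term, a log2 ratio of at least 1, no empirical Bayes step, fry, and leaving out each culture at each time and each array. Slides were recognised from the 0 min channel: 7 of 10 slides held more than 1 sample, up to 3, with correlations of at least 0.933 within a slide and at most 0.542 between slides. The labels give 7 hybridization days. A 10 min and a 30 min sample of culture 2 on 1 slide appear from that channel to share it and carry the same dye label, and leaving both out was an alternative chosen after seeing the data. So was leaving out genes near background, under 2 times the local background in the sample channel in all spots and arrays of a time.

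Ratios were simulated for the 2192 genes with 200 changed. Against 0 min the fit recovered 64% to 66% of genes changed by 1 on the log2 scale and 91% of those changed by 2, with 4.85% to 9.36% of calls false. With culture as a block it recovered 79% to 83% and 95% to 97%, with 19.1% to 22.3% of calls false. For 60 min against 10 min recovery was 45% and 80% with 2.34% false, and with the block 64% and 90% with 4.94% false. In the list test the shifted list had adjusted p = 3.87e-62 and 0 of 130 other tests passed at 0.05. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.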

Results

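Pyrococcus furiosus is a hyperthermophilic archaeon that ferments sugars and peptides, releasing hydrogen, and makes sulfide instead when elemental sulfur is present. The arrays followed its RNA after sulfur (2 g/l) was stirred into cultures growing on maltose (5 g/l) with yeast extract (0.5 g/l) in a 20 l fermentor. The time course was run on 2 cultures, and each was sampled before sulfur (0 min) and at 10, 20, 30 and 60 min. An array here is 1 sample, with RNA from 1 of the later times beside the 0 min RNA of the same culture. There were 18 arrays: 4 each for 10, 20 and 60 min and 6 for 30 min, divided equally between the cultures. From the 0 min channel these appear to lie on 10 slides, with up to 3 on 1 slide. Arrays of 1 slide may share its 0 min reading and are then not fully separate. Each array held 2192 genes in 3 spots each.

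Signal was well over background on most spots. The median spot signal per array ran from 6246 to 14332 scanner units in the 0 min channel and from 8735.5 to 25027 in the sample channel. Between 77.8% and 94.5% of spots per array exceeded 2 times the local background in both channels. Across genes, which are not independent replicates, the log2 ratios of the 2 cultures correlated with r = 0.689 at 10 min, 0.648 at 20 min, 0.729 at 30 min and 0.719 at 60 min. Values written with ± are log2 ratios of sample over 0 min, relative to the bulk of genes on the same array, with the SE of the limma model (n = 2 cultures). The small number of cultures limits their precision. In all comparisons with 0 min, that RNA carried Alexa 647 on every array, so a gene-specific bias of this dye can be part of any single ratio there. A bias that is the same on every array cancels in the comparison of 60 min with 10 min.

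The question at 10 min was which transcripts moved soonest after sulfur. By limma 12 of 14 membrane-bound hydrogenase genes and all 4 genes of hydrogenase II fell, and 12 of 13 genes of the mbx cluster rose. Their 3 lists passed camera and lost that call, at adjusted p = 0.224 to 0.244 with an estimated correlation. By fry they passed, at adjusted p = 0.00075 to 0.0011. The 14 genes of the membrane-bound hydrogenase, which evolves hydrogen from electrons carried by ferredoxin, had a median 6.1-fold lower (log2 -2.61). The 13 genes of the mbx cluster, whose product resembles that hydrogenase and is tied to sulfur reduction, had a median 7.2-fold higher (log2 2.85). In total 80 of 2192 genes passed the limma threshold, 41 higher and 39 lower. With culture as a block 225 passed, and 414 had an unadjusted p under 0.05.

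Among the mbx genes, 12 of 13 rose (12 adjusted over the list alone), with camera adjusted p = 9.88e-18, and adjusted p = 0.231 with an estimated correlation. The 5 highest called genes on the array all lay in this cluster. They were PF1444, annotated as an NADH dehydrogenase subunit, at 3.47 ± 0.23 (11.1-fold, adjusted p = 0.00081), PF1451 at 3.45 ± 0.32, PF1452 at 3.40 ± 0.36, PF1450 at 3.23 ± 0.48 and PF1448 at 3.06 ± 0.30. PF1442 rose by 2.61 ± 0.29 and PF1453 by 2.85 ± 0.27 (adjusted p = 0.00209). The member that did not pass was PF1443, named after its values were seen, at -0.21.

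Hydrogenase genes were among the lowest. Of the membrane-bound hydrogenase genes 12 of 14 fell (14 adjusted over the list alone), with camera adjusted p = 3.31e-21, and adjusted p = 0.224 with an estimated correlation. PF1426 (mbh4) stood at -3.13 ± 0.22, PF1424 (mbh2) at -2.99 ± 0.30, PF1427 (mbh5) at -2.90 ± 0.19, PF1428 (mbh6) at -2.89 ± 0.16 and PF1434 (mbh12, the catalytic subunit) at -2.24 ± 0.22 (adjusted p = 0.00226). All 4 genes of cytoplasmic hydrogenase II fell, also adjusted over the list alone, with camera adjusted p = 3.62e-08, and adjusted p = 0.244 with an estimated correlation. Among them PF1329 (beta) was 9.64-fold lower at -3.27 ± 0.28, PF1331 (delta) stood at -3.23 ± 0.26, PF1330 (gamma) at -3.08 ± 0.15 and PF1332 (alpha) at -2.15 ± 0.33. Cytoplasmic hydrogenase I had 1 lower and 3 not called of 4 genes, 3 lower adjusted over the list alone, 4 lower with culture as a block, with median -2.33, camera adjusted p = 0.00138, and adjusted p = 0.387 with an estimated correlation. Its gamma subunit gene PF0892 fell to -2.58 ± 0.46, while the alpha subunit gene PF0894 had -1.69 ± 0.81 and did not pass (adjusted p = 0.328, and 0.0232 with culture as a block). The hydrogenase maturation list (median -0.28) also tested lower, with camera adjusted p = 0.0128, and adjusted p = 0.489 with an estimated correlation. The called gene was PF0559, annotated as a hydrogenase expression regulator, at -2.99 ± 0.23, with 1 lower and 6 not called of 7 genes, 1 lower adjusted over the list alone. The lowest of all called genes was PF0925, annotated as a heme biosynthesis protein, at -3.37 ± 0.37 (10.3-fold lower, adjusted p = 0.00337).

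Of 5 genes tied to sulfur in earlier work, 3 rose by 10 min (3 adjusted over the list alone, median 1.28), with camera adjusted p = 0.0018, and adjusted p = 0.244 with an estimated correlation. They were PF0094, a glutaredoxin-like protein, at 2.08 ± 0.17, PF1186, annotated as an NADH oxidase and known as a coenzyme A-dependent sulfur oxidoreductase, at 1.85 ± 0.17, and PF0095, known as the redox-sensing regulator SurR, at 1.28 ± 0.18. PF2025 and PF2026 had 0.03 ± 0.33 and -0.26 ± 0.21 and did not pass (adjusted p = 0.98 and 0.592). Part of what was known of these genes, of mbx and of the hydrogenases came from the study of these same samples, so their lists are not independent evidence of direction.

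Ribosomal proteins had 5 higher and 61 not called of 66 genes, 21 higher adjusted over the list alone, 16 higher with culture as a block (median 0.59), with camera adjusted p = 9.88e-18, and adjusted p = 0.315 with an estimated correlation. Examples were PF1823 (L23) at 1.29 ± 0.26, PF1824 (L4) at 1.26 ± 0.24, PF1818 (L29) at 1.24 ± 0.21 and PF1809 (S8) at 1.13 ± 0.21. Among RNA polymerase subunits (median 0.72) the count was 1 higher and 10 not called of 11 genes, 2 higher adjusted over the list alone, 4 higher with culture as a block, with camera adjusted p = 0.000101, and adjusted p = 0.409 with an estimated correlation. The riser was PF0986 (subunit M) at 1.04 ± 0.20. For aminoacyl-tRNA synthetases (median 0.35) it was 1 higher and 25 not called of 26 genes, 1 higher adjusted over the list alone, 3 higher with culture as a block, with camera adjusted p = 0.000502, and adjusted p = 0.231 with an estimated correlation. PF0155, for asparagine, stood at 1.08 ± 0.19. Methionine synthesis had 2 higher and 2 not called of 4 genes, 3 higher adjusted over the list alone (median 1.02), with camera adjusted p = 0.000386, and adjusted p = 0.244 with an estimated correlation. PF1266, annotated as a cystathionine gamma-lyase, was at 1.52 ± 0.17 and PF1268 at 1.36 ± 0.24. Branched-chain amino acid synthesis (median 0.68) tested higher, with 0 of 9 genes called by limma, 5 at an unadjusted p under 0.05, 1 higher adjusted over the list alone, 1 higher with culture as a block, camera adjusted p = 0.000351, and adjusted p = 0.371 with an estimated correlation. Histidine synthesis (median 0.46) also did, with 0 of 9 genes called by limma, 5 at an unadjusted p under 0.05, 2 higher adjusted over the list alone, 2 higher with culture as a block, camera adjusted p = 0.000485, and adjusted p = 0.392 with an estimated correlation. Glycolysis and gluconeogenesis was just past the threshold (median 0.25, 1 higher and 12 not called of 13 genes, 1 higher adjusted over the list alone, 1 higher and 1 lower with culture as a block), with camera adjusted p = 0.0309, and adjusted p = 0.387 with an estimated correlation, and with culture as a block it did not pass (adjusted p = 0.0556). Its riser was PF1784, the ADP-dependent phosphofructokinase, at 0.96 ± 0.19.

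In lists that did not pass, PF0450, glutamine synthetase, fell to -2.38 ± 0.23 and PF1033, an alkyl hydroperoxide reductase, rose to 1.30 ± 0.18. The ferredoxin gene PF1909 had -0.03 ± 0.19 (adjusted p = 0.975). In all 14 lists did not pass, among them oxidative stress (median 0.24, camera adjusted p = 0.0783), heat shock and stress (-0.35, 0.0929), transposases (-0.13, 0.0585, and 0.0313 without culture 1), archaeal ATP synthase (0.20, 0.195) and maltose uptake and use (-0.0037, 0.852). Iron uptake and storage had a median of 0.02, a mean of -0.12 and a test pointing down (0.595). The count of 80 fell to 31 without the 10 min arrays of culture 1 and to 27 without those of culture 2, where the glycolysis and hydrogenase maturation lists lost their call (adjusted p = 0.123 and 0.0714), as glycolysis did without culture 2 at 60 min (0.0508). Transposases also passed without either culture at 20 min (0.0423 and 0.0417), and the 2-oxoacid oxidoreductases (median 0.15, 0.411) without culture 1 at 10 min (0.45, 0.00615). Calls lost with another normalization, background or spot filter setting or in the authors' deposited table were those of the lists aminoacyl-tRNA synthetases, glycolysis and gluconeogenesis and hydrogenase maturation, and of PF0986, PF1784, PF1809, PF1823 and PF1824.

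**Figure D1:**
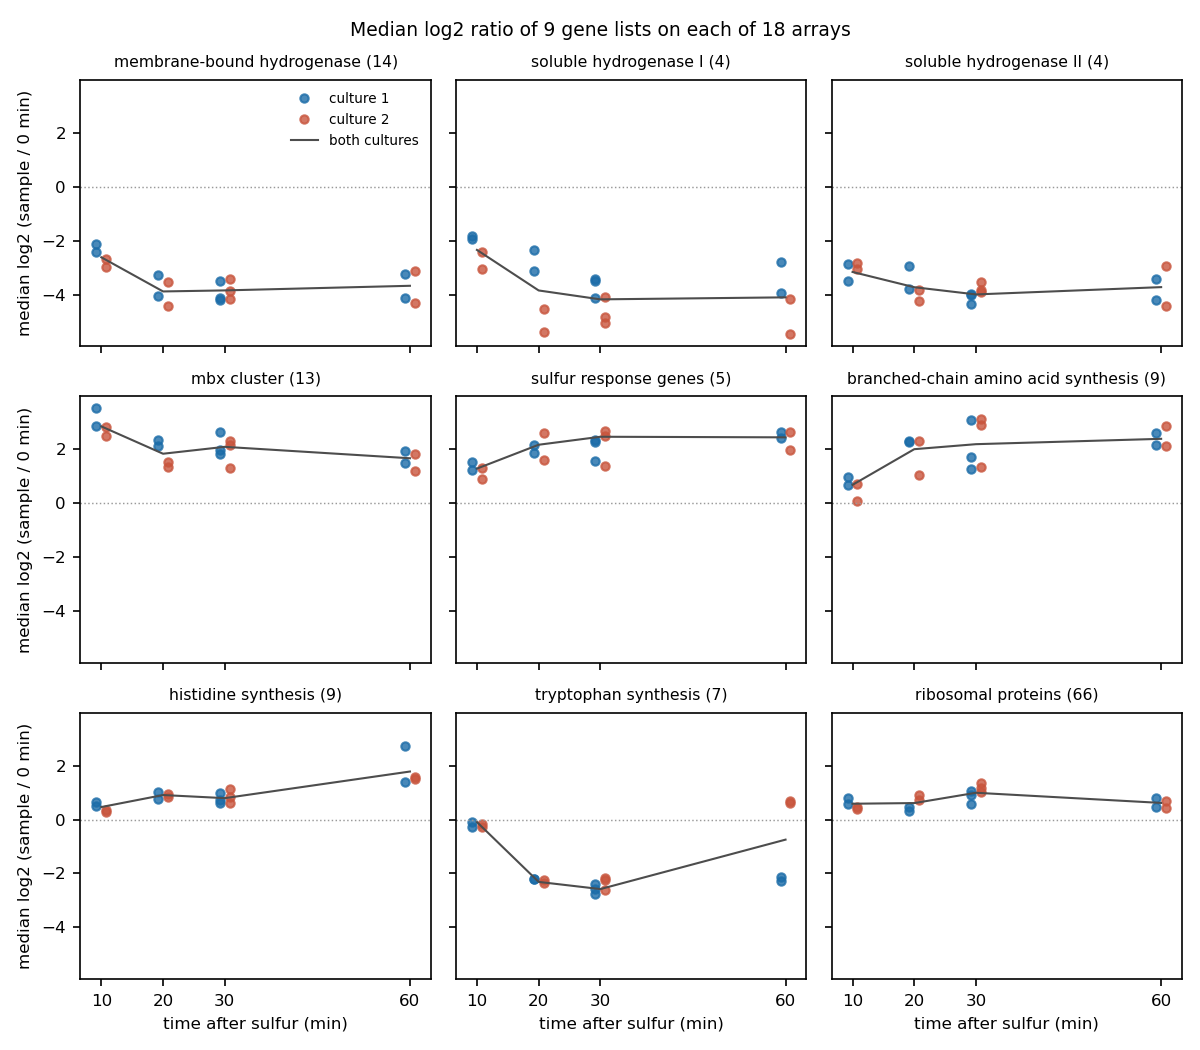
Median log2 ratio of sample over 0 min for 9 gene lists (number of genes in brackets) against time after sulfur in minutes, with each point 1 of 18 arrays, coloured and offset sideways by culture, and a line joining the medians of the limma estimates. The hydrogenase lists lie below 0 and the mbx list above 0 on every array, and the tryptophan points of the cultures part at 60 min (medians -2.08 and 0.60).

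At 20 min the question was how the response had spread. By limma all 14 membrane-bound hydrogenase genes, 5 of 7 tryptophan genes and 9 of 13 maltose genes fell, and 12 of 13 mbx genes and all 9 branched-chain genes rose. These 5 lists passed camera and lost that call, at adjusted p = 0.224 to 0.409 with an estimated correlation. Branched-chain amino acid synthesis had a median 4.01-fold higher (log2 2.00), whereas tryptophan synthesis had a median 4.96-fold lower (log2 -2.31) and maltose uptake and use 2.42-fold lower (log2 -1.27). PF2025 was 9.32-fold higher and PF2026 6.76-fold higher. By limma 422 genes passed, 212 higher and 210 lower. With culture as a block 800 passed.

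The highest called genes were PF2025 at 3.22 ± 0.33 (adjusted p = 0.00184, and 3.92 or 2.52 without array a or b of culture 1), PF2026, annotated as a polyferredoxin, at 2.76 ± 0.21 (0.00043), PF1450 at 2.40 ± 0.48 (3.25 in culture 1 and 1.54 in culture 2), PF0262, annotated as a transporter of the major facilitator superfamily, at 2.38 ± 0.16, and PF1446 at 2.33 ± 0.23. With PF1186 at 2.17 ± 0.17, PF0094 at 1.76 ± 0.17 and PF0095 at 0.76 ± 0.18, all 5 genes known for sulfur had risen, also adjusted over the list alone, with median 2.17, camera adjusted p = 1.31e-05, and adjusted p = 0.231 with an estimated correlation. The mbx genes stood at a median of 1.84, with 12 higher and 1 not called of 13 genes, 12 higher adjusted over the list alone, with camera adjusted p = 4.19e-08, and adjusted p = 0.244 with an estimated correlation. PF1448 was at 2.17 ± 0.30, PF1449 at 2.12 ± 0.22, PF1442 at 1.45 ± 0.29 and PF1453 at 1.20 ± 0.27.

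All 14 membrane-bound hydrogenase genes fell (14 adjusted over the list alone, median -3.87, or 14.7-fold lower), with camera adjusted p = 9.88e-18, and adjusted p = 0.224 with an estimated correlation. PF1431 (mbh9) stood at -4.33 ± 0.28, PF1426 at -4.27 ± 0.22, PF1424 at -4.21 ± 0.30, PF1423 (mbh1) at -4.13 ± 0.21 and PF1434 at -3.29 ± 0.22. Hydrogenase I had 3 lower and 1 not called of 4 genes, 4 lower adjusted over the list alone, with median -3.84 (-2.72 in culture 1 and -4.96 in culture 2), camera adjusted p = 0.00141, and adjusted p = 0.387 with an estimated correlation. PF0892 was at -4.25 ± 0.46 (19.1-fold lower), PF0893 (delta) at -3.91 ± 0.53 and PF0891 (beta) at -3.76 ± 0.65. In cultures 1 and 2 these had -3.38 and -5.12, -2.91 and -4.91, and -2.52 and -5.00. PF0894 had -2.54 ± 0.81 without passing (adjusted p = 0.0711, and 0.00207 with culture as a block). In hydrogenase II all 4 genes fell, also adjusted over the list alone (median -3.72), with camera adjusted p = 6.89e-06, and adjusted p = 0.244 with an estimated correlation. These included PF1331 at -3.86 ± 0.26 and PF1332 at -2.99 ± 0.33. PF0559 stood at -3.57 ± 0.23, although its maturation list did not pass (median -0.22, camera adjusted p = 0.11, and 0.0308 without culture 1). Among the lowest called genes was also PF0736.1, which has no product name in the files, at -4.16 ± 0.24 (17.8-fold lower).

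Lists of amino acid pathways tested higher in some cases and lower in others. All 9 branched-chain genes PF0934 to PF0942 rose, also adjusted over the list alone, with camera adjusted p = 3.62e-08, and adjusted p = 0.244 with an estimated correlation. Their median was 1.04 on array b of culture 2, against 2.27 to 2.32 on the other arrays. Acetolactate synthase PF0935 was at 2.24 ± 0.27, ketol-acid reductoisomerase PF0936 at 2.24 ± 0.30, PF0939 at 2.16 ± 0.16 and PF0941 at 2.02 ± 0.18. Histidine synthesis had 8 higher and 1 not called of 9 genes, 8 higher adjusted over the list alone (median 0.91), with camera adjusted p = 2.64e-05, and adjusted p = 0.371 with an estimated correlation. Histidinol dehydrogenase PF1659 stood at 1.17 ± 0.15, ATP phosphoribosyltransferase PF1658 at 1.13 ± 0.20, PF1661 at 1.13 ± 0.27 and PF1660 at 1.004 ± 0.26. Tryptophan synthesis had 5 lower and 2 not called of 7 genes, 7 lower adjusted over the list alone, with camera adjusted p = 0.000807, and adjusted p = 0.409 with an estimated correlation. Examples were anthranilate synthase component I PF1709 at -2.62 ± 0.53, PF1711 at -2.39 ± 0.50, PF1710 at -2.31 ± 0.62 and PF1706 at -2.06 ± 0.55. The aromatic list had 5 lower and 9 not called of 14 genes, 5 lower adjusted over the list alone (median -1.05), with camera adjusted p = 0.00431, and adjusted p = 0.389 with an estimated correlation. It included prephenate dehydrogenase PF1703 at -1.92 ± 0.36, PF1692 at -1.87 ± 0.40 (-2.46 in culture 1 and -1.28 in culture 2), PF1702 at -1.52 ± 0.31 and PF1691 at -1.34 ± 0.31. Glutamine synthetase PF0450 fell to -2.62 ± 0.23 and glutamate dehydrogenase PF1602 to -2.18 ± 0.31. Their list of 5 had a median of 1.03, a mean of -0.12 and a test pointing down, and it did not pass (camera adjusted p = 0.716). PF1687 of the arginine and lysine list fell to -2.04 ± 0.35, while that list did not pass (median -0.52, 0.218, and -1.44, 0.0435 without culture 1).

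Genes for taking up and breaking maltose down tested lower, with 9 lower and 4 not called of 13 genes, 11 lower adjusted over the list alone, camera adjusted p = 5e-06, and adjusted p = 0.341 with an estimated correlation. PF1937 and PF1936, annotated as sugar transport membrane proteins, stood at -2.50 ± 0.57 and -2.25 ± 0.37, the sugar-binding protein PF1938 at -2.23 ± 0.38 and amylopullulanase PF1935 at -2.22 ± 0.51. The 2-oxoacid ferredoxin oxidoreductases, which oxidise pyruvate and related acids, had 5 lower and 11 not called of 16 genes, 7 lower adjusted over the list alone, 8 lower with culture as a block (median -0.69), with camera adjusted p = 0.00748, and adjusted p = 0.494 with an estimated correlation. PF0967 was at -1.84 ± 0.30 (-2.50 in culture 1 and -1.18 in culture 2), PF0971 at -1.45 ± 0.19, PF0966 at -1.42 ± 0.21 and PF0968 at -1.37 ± 0.28. PF0196 of the glycolysis list fell to -0.98 ± 0.19 and PF1837 of the acetyl-CoA synthetase list to -0.91 ± 0.19, and neither list passed (medians -0.03 and -0.81, camera adjusted p = 0.641 and 0.302). Ferredoxin PF1909 fell to -1.77 ± 0.19 (adjusted p = 0.00215).

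Ribosomal protein genes had 17 higher and 49 not called of 66 genes, 36 higher adjusted over the list alone, 37 higher with culture as a block (median 0.61), with camera adjusted p = 1.69e-11, and adjusted p = 0.387 with an estimated correlation. PF1810 (S14) stood at 1.54 ± 0.24, PF0252 (S27AE) at 1.33 ± 0.19, PF0376 at 1.31 ± 0.21 and PF0399 at 1.27 ± 0.25. For RNA polymerase it was 3 higher and 8 not called of 11 genes, 3 higher adjusted over the list alone (median 0.57), with camera adjusted p = 0.00622, and adjusted p = 0.553 with an estimated correlation. PF0986 was at 1.73 ± 0.20, PF1642 at 1.13 ± 0.25 and PF1643 at 0.84 ± 0.21, and the list was not past the threshold without culture 2 (median 0.08, adjusted p = 0.53), against a median of 1.23 without culture 1. The archaellum list, genes of the swimming filament, had 2 higher and 5 not called of 7 genes, 5 higher adjusted over the list alone, 5 higher with culture as a block (median 0.61), with camera adjusted p = 0.0117, and adjusted p = 0.244 with an estimated correlation. PF0335 and PF0332 stood at 0.75 ± 0.18 and 0.61 ± 0.15. Aminoacyl-tRNA synthetases did not pass (median 0.34, 0.0736, and 0.0428 without culture 2), and PF0869 and PF1096 in it rose to 0.70 ± 0.19 and 0.65 ± 0.17. In the oxidative stress list PF1033 rose to 0.68 ± 0.18, PF0751, a flavoprotein, fell to -1.03 ± 0.15 and PF1197 fell to -1.51 ± 0.21, and the list did not pass (median -0.79, 0.119, and 0.0179 without culture 2). The iron transporter gene PF0857 rose to 0.99 ± 0.28 (0.37 in culture 1 and 1.62 in culture 2), and its list did not pass (median 0.07, 0.716).

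The count of 422 was 141 without the 20 min arrays of culture 1 and 122 without those of culture 2, and 256 where either culture was left out at 10 min. Calls lost with another normalization, background or spot filter setting or in the authors' deposited table were those of PF0095, PF0332, PF0335, PF0857, PF0869, PF1033, PF1096, PF1642, PF1643 and PF1706, and those lost only with a random block or a sample dye term over 18 arrays were PF1453 and PF1837.

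The 30 min samples, with 3 arrays per culture, addressed the same question at the most densely sampled time. By limma all 14 membrane-bound hydrogenase and all 7 tryptophan genes fell, while all 9 branched-chain genes, all 5 sulfur genes and 47 of 66 ribosomal protein genes rose. Those 5 lists passed camera and lost that call, at adjusted p = 0.224 to 0.409 with an estimated correlation. The ribosomal protein list had a median 1.99-fold higher and the branched-chain list 4.56-fold higher, against 14.3-fold lower for the membrane-bound hydrogenase and 5.97-fold lower for tryptophan synthesis. By limma 484 genes passed, 258 higher and 226 lower, and 853 passed with culture as a block. The share of calls that were higher, 53.3%, was 42.2% in the authors' deposited table, whose values are not centred and whose median gene lay at -0.11.

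The highest called genes were PF2026 at 3.04 ± 0.21 (adjusted p = 0.000262), PF2025 at 2.90 ± 0.33 (2.29 without array b of culture 1), PF1679, annotated as a 3-isopropylmalate dehydratase large subunit, at 2.81 ± 0.56 (4.19 in culture 1 and 1.44 in culture 2), PF1678, annotated as a 2-isopropylmalate synthase, at 2.64 ± 0.56 (3.96 and 1.33), and PF0937, another gene so annotated, at 2.60 ± 0.24. In the sulfur list all 5 rose, also adjusted over the list alone (median 2.46), with camera adjusted p = 7.72e-06, and adjusted p = 0.231 with an estimated correlation. Among them were PF0094 at 2.46 ± 0.17, PF1186 at 2.10 ± 0.17 and PF0095 at 1.09 ± 0.18. The mbx cluster had 12 higher and 1 not called of 13 genes, 12 higher adjusted over the list alone (median 2.09), with camera adjusted p = 1.35e-08, and adjusted p = 0.244 with an estimated correlation. PF1451 stood at 2.43 ± 0.32, PF1446 at 2.40 ± 0.23, PF1444 at 2.30 ± 0.23, PF1447 at 2.24 ± 0.38, PF1453 at 1.86 ± 0.27 and PF1442 at 1.81 ± 0.29.

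Lowest were PF0892 at -4.53 ± 0.46 (23.1-fold lower), PF1431 at -4.30 ± 0.28, PF0893 at -4.28 ± 0.53, PF1426 at -4.26 ± 0.22 and PF0736.1 at -4.25 ± 0.24. The membrane-bound hydrogenase genes all fell (14 adjusted over the list alone, median -3.83), with camera adjusted p = 9.57e-17, and adjusted p = 0.224 with an estimated correlation. Members included PF1428 at -4.05 ± 0.16, PF1430 at -4.03 ± 0.26 and PF1434 at -3.61 ± 0.22. Hydrogenase I had 3 lower and 1 not called of 4 genes, 4 lower adjusted over the list alone (median -4.17), with camera adjusted p = 0.00155, and adjusted p = 0.387 with an estimated correlation. PF0891 was at -4.05 ± 0.65 and PF0894, which did not pass, at -2.69 ± 0.81 (adjusted p = 0.0573, and 0.00134 with culture as a block). All 4 hydrogenase II genes fell, also adjusted over the list alone (median -3.98), with camera adjusted p = 9.4e-06, and adjusted p = 0.244 with an estimated correlation. Examples were PF1331 at -4.10 ± 0.26 and PF1332 at -3.38 ± 0.33. PF0559 fell to -3.79 ± 0.23, and its list had a camera adjusted p of 0.0516, or 0.0309 with culture as a block and 0.0223 without culture 1 (median -0.31). It also passed without either culture at 20 min (0.0423 and 0.0417) and without culture 1 at 60 min (0.0486). PF1327, a ferredoxin NADP oxidoreductase subunit, fell to -2.00 ± 0.52, and its list did not pass (median -0.95, 0.302). Ferredoxin PF1909 fell to -0.90 ± 0.19.

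All 9 branched-chain genes rose, also adjusted over the list alone, with camera adjusted p = 1.55e-08, and adjusted p = 0.244 with an estimated correlation. PF0936 stood at 2.56 ± 0.30, PF0935 at 2.50 ± 0.27 and PF0939 at 2.39 ± 0.16. Histidine synthesis had 8 higher and 1 not called of 9 genes, 8 higher adjusted over the list alone (median 0.79), with camera adjusted p = 0.000175, and adjusted p = 0.387 with an estimated correlation. PF1665, annotated as a histidinol-phosphate aminotransferase, was at 1.18 ± 0.17 and PF1661 at 1.01 ± 0.27. Methionine synthesis had 3 higher and 1 not called of 4 genes, 3 higher adjusted over the list alone (median 0.98), with camera adjusted p = 0.00726, and adjusted p = 0.315 with an estimated correlation. PF1266 was at 1.72 ± 0.17, PF1268 at 1.24 ± 0.24 and PF1267 at 0.72 ± 0.20. All 7 tryptophan genes fell, also adjusted over the list alone (median -2.58), with camera adjusted p = 0.000707, and adjusted p = 0.409 with an estimated correlation. PF1709 stood at -2.93 ± 0.53, PF1707 at -2.67 ± 0.65, PF1708 at -2.63 ± 0.71 and PF1711 at -2.58 ± 0.50 (-1.81 in culture 1 and -3.34 in culture 2). The aromatic list had 4 lower and 10 not called of 14 genes, 4 lower adjusted over the list alone, 7 lower with culture as a block (median -0.83), with camera adjusted p = 0.00344, and adjusted p = 0.389 with an estimated correlation. These included PF1692 at -1.84 ± 0.40 and PF1703 at -1.66 ± 0.36. Glutamine synthetase PF0450 was at -3.20 ± 0.23 and glutamate dehydrogenase PF1602 at -2.14 ± 0.31, whereas PF0204 and PF0206, neighbours of glutamate synthase subunit gene PF0205, rose to 2.20 ± 0.59 and 1.89 ± 0.55. In cultures 1 and 2 these had 3.50 and 0.90, and 3.04 and 0.74. That list did not pass, with median 1.70, mean 0.09 and a test pointing down (camera adjusted p = 0.912). The arginine and lysine list did not pass either (0.305), and the cultures lay apart in it, with medians of 0.79 in culture 1 and -1.68 in culture 2. It passed as lower without culture 1 (0.00144).

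The ribosomal protein list had 47 higher and 19 not called of 66 genes, 56 higher adjusted over the list alone (median 0.99), with camera adjusted p = 1.76e-19, and adjusted p = 0.297 with an estimated correlation. PF1824 stood at 2.00 ± 0.24 (4-fold), PF1823 at 1.72 ± 0.26, PF1810 at 1.66 ± 0.24 and PF0218 (S27E) at 1.63 ± 0.29. RNA polymerase had 7 higher and 4 not called of 11 genes, 9 higher adjusted over the list alone (median 1.22), with camera adjusted p = 3.57e-05, and adjusted p = 0.404 with an estimated correlation. The called genes included PF0986 at 2.08 ± 0.20 and PF1564 (subunit B) at 1.35 ± 0.33. Aminoacyl-tRNA synthetases had 4 higher and 22 not called of 26 genes, 2 higher adjusted over the list alone, 11 higher with culture as a block (median 0.36), with camera adjusted p = 0.00748, and adjusted p = 0.244 with an estimated correlation. PF0155 was at 1.17 ± 0.19. The archaellum list had 1 higher and 6 not called of 7 genes, 4 higher adjusted over the list alone, 4 higher with culture as a block (median 0.52), with camera adjusted p = 0.0255, and adjusted p = 0.277 with an estimated correlation. The gene was PF0332 at 0.55 ± 0.15.

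Maltose uptake and use had 7 lower and 6 not called of 13 genes, 8 lower adjusted over the list alone (median -0.85), with camera adjusted p = 0.00153, and adjusted p = 0.409 with an estimated correlation. Among them were PF1937 at -2.41 ± 0.57, PF1936 at -2.24 ± 0.37 and PF1935 at -2.02 ± 0.51. The 2-oxoacid ferredoxin oxidoreductase list did not pass (median -0.25, 0.211). In other lists that did not pass, the iron transporter gene PF0857 rose to 1.78 ± 0.28, PF1033 rose to 1.43 ± 0.18, PF1197 fell to -1.86 ± 0.21, PF0613 of gluconeogenesis fell to -2.07 ± 0.51 (-2.79 in culture 1 and -1.34 in culture 2), and PF0532 fell to -1.85 ± 0.49 (-1.24 and -2.46) while PF1540, an ADP-forming acetyl-CoA synthetase, rose to 0.80 ± 0.17. Archaeal ATP synthase had a median of 0.38 (camera adjusted p = 0.122, and 0.0382 with culture as a block), but the cultures had opposite signs, with -0.16 in culture 1 and 1.01 in culture 2, and without culture 1 it passed (adjusted p = 0.00392). The count of 484 was 154 without the 30 min arrays of culture 1, where the archaellum list lost its call (adjusted p = 0.0843), 85 without those of culture 2, and 310 where either culture was left out at 10 min. Calls lost with another normalization, background or spot filter setting or in the authors' deposited table were those of the list aminoacyl-tRNA synthetases, and of PF0206, PF0332, PF0532, PF1267, PF1327, PF1540, PF1564 and PF1661.

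**Figure D2:**
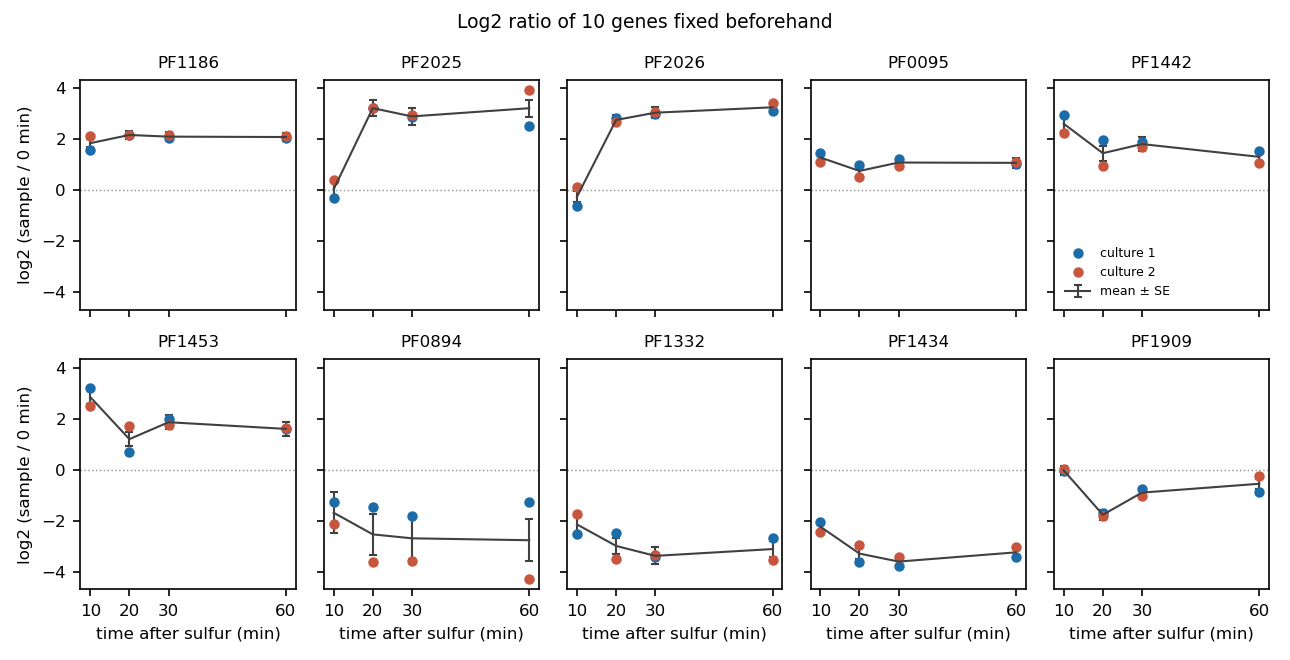
Log2 ratio of sample over 0 min for 10 genes fixed before the data were examined, against time after sulfur in minutes, with points for the 2 cultures and lines joining the means with the SE of the limma model. Means of PF2025 and PF2026 lie near 0 at 10 min (0.03 and -0.26) and near 3 from 20 min on, while PF1332 and PF1434 lie below -2 at all times.

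The 60 min samples gave the latest state measured. By limma all 14 membrane-bound hydrogenase genes fell, with a median 12.7-fold lower, and 12 of 13 mbx, all 5 sulfur, all 9 branched-chain and all 9 histidine genes rose. Their 5 lists passed camera and lost that call, at adjusted p = 0.224 to 0.244 with an estimated correlation. Histidine synthesis stood 3.43-fold and branched-chain synthesis 5.23-fold higher at the median. Tryptophan synthesis did not pass, and the cultures had opposite signs there. By limma 359 genes passed, 185 higher and 174 lower, and 690 passed with culture as a block.

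The highest called genes were PF1679 at 3.44 ± 0.56 (10.8-fold), PF0204 at 3.26 ± 0.59, PF2026 at 3.25 ± 0.21, PF2025 at 3.22 ± 0.33 (2.52 in culture 1 and 3.92 in culture 2) and PF1680, annotated as the small subunit beside PF1679, at 3.16 ± 0.56 (2.25 and 4.07). The sulfur list rose in all 5 genes, also adjusted over the list alone (median 2.44), with camera adjusted p = 2.51e-06, and adjusted p = 0.231 with an estimated correlation. PF0094 stood at 2.44 ± 0.17, PF1186 at 2.09 ± 0.17 and PF0095 at 1.07 ± 0.18. The mbx cluster had 12 higher and 1 not called of 13 genes, 12 higher adjusted over the list alone (median 1.67), with camera adjusted p = 1.35e-08, and adjusted p = 0.244 with an estimated correlation. PF1451 was at 2.14 ± 0.32, PF1446 at 2.00 ± 0.23, PF1453 at 1.60 ± 0.27 and PF1442 at 1.31 ± 0.29. Lowest were PF0892 at -4.42 ± 0.46, PF1431 at -4.20 ± 0.28, PF0736 at -4.13 ± 0.27, PF0893 at -4.09 ± 0.53 (-3.44 in culture 1 and -4.75 in culture 2) and PF0891 at -4.09 ± 0.65 (-3.30 and -4.88). The membrane-bound hydrogenase genes all fell (14 adjusted over the list alone, median -3.66), with camera adjusted p = 1.68e-17, and adjusted p = 0.224 with an estimated correlation. These included PF1434 at -3.24 ± 0.22. Hydrogenase I had 3 lower and 1 not called of 4 genes, 4 lower adjusted over the list alone (median -4.09, with -3.37 in culture 1 and -4.81 in culture 2), with camera adjusted p = 0.0011, and adjusted p = 0.387 with an estimated correlation. PF0894 had -2.77 ± 0.81 without passing (adjusted p = 0.0641, and 0.00106 with culture as a block). All 4 hydrogenase II genes fell, also adjusted over the list alone (median -3.71), with camera adjusted p = 6.65e-06, and adjusted p = 0.244 with an estimated correlation. PF1332 was at -3.11 ± 0.33. PF0559 stood at -3.53 ± 0.23, and its list had a camera adjusted p of 0.0687, or 0.0404 with culture as a block (median -0.31, with 0.03 in culture 1 and -0.60 in culture 2). It passed without culture 1 (0.0085).

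All 9 histidine genes rose, also adjusted over the list alone, with camera adjusted p = 6.48e-09, and adjusted p = 0.244 with an estimated correlation. Their median was 2.73 on array b of culture 1, against 1.40 to 1.56 on the other arrays. PF1665 was at 1.99 ± 0.17, PF1661 at 1.99 ± 0.27 and PF1660 at 1.88 ± 0.26. The list includes PF1657, annotated as a histidyl-tRNA synthetase, at 1.07 ± 0.17. All 9 branched-chain genes rose, also adjusted over the list alone, with camera adjusted p = 2.55e-09, and adjusted p = 0.244 with an estimated correlation. Among them were PF0937 at 2.96 ± 0.24 and PF0935 at 2.71 ± 0.27. Methionine synthesis had 1 higher and 3 not called of 4 genes, 3 higher adjusted over the list alone, 2 higher with culture as a block (median 0.75), with camera adjusted p = 0.0202, and adjusted p = 0.371 with an estimated correlation. The gene was PF1266 at 1.22 ± 0.17. Tryptophan synthesis had a median of -2.08 in culture 1 and 0.60 in culture 2 (camera adjusted p = 0.241 over both, 0.0085 and higher without culture 1, 2.18e-07 and lower without culture 2). The aromatic list had 0.53 (0.108), with 0.05 in culture 1 and 1.04 in culture 2, and it passed as higher without culture 1 (0.000949). In glutamate metabolism PF0204 was joined by PF0205 at 2.65 ± 0.57 and PF0206 at 2.75 ± 0.55, while PF0450 stood at -2.43 ± 0.23. That list did not pass (median 2.65, 0.762), nor did arginine and lysine synthesis (median 0.59, 0.433).

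Ribosomal protein genes had 20 higher and 46 not called of 66 genes, 30 higher adjusted over the list alone, 34 higher with culture as a block (median 0.62), with camera adjusted p = 4.41e-12, and adjusted p = 0.387 with an estimated correlation. Examples were PF1810 at 1.52 ± 0.24 and PF1824 at 1.32 ± 0.24. RNA polymerase had 2 higher and 9 not called of 11 genes, 5 higher adjusted over the list alone, 6 higher with culture as a block (median 0.83), with camera adjusted p = 0.000954, and adjusted p = 0.489 with an estimated correlation. PF0986 stood at 2.38 ± 0.20. Aminoacyl-tRNA synthetases had 4 higher and 22 not called of 26 genes, 4 higher adjusted over the list alone, 8 higher with culture as a block (median 0.40), with camera adjusted p = 0.00107, and adjusted p = 0.231 with an estimated correlation. The leading gene was PF0155 at 1.47 ± 0.19. Archaellum genes had 0 of 7 genes called by limma, 4 at an unadjusted p under 0.05, 0 adjusted over the list alone, 3 higher with culture as a block (median 0.38), with camera adjusted p = 0.0294, and adjusted p = 0.287 with an estimated correlation. Maltose uptake and use had 4 lower and 9 not called of 13 genes, 9 lower adjusted over the list alone, 11 lower with culture as a block (median -0.95), with camera adjusted p = 0.000146, and adjusted p = 0.387 with an estimated correlation. These included alpha-amylase PF0272 at -1.07 ± 0.21 and the trehalose and maltose transport genes PF1740 at -0.95 ± 0.19 and PF1741 at -0.88 ± 0.15. The 2-oxoacid ferredoxin oxidoreductases had 6 lower and 10 not called of 16 genes, 7 lower adjusted over the list alone (median -0.84), with camera adjusted p = 0.044, and adjusted p = 0.604 with an estimated correlation. The called genes included PF0967 at -1.45 ± 0.30 and PF0971 at -1.27 ± 0.19. That list was not past the threshold without culture 2 (median -0.17, adjusted p = 0.72), nor without either culture at 10 min (0.0527 and 0.0568). Transposases tested slightly lower, with 0 of 28 genes called by limma, 4 at an unadjusted p under 0.05, 0 adjusted over the list alone, 4 lower with culture as a block (median -0.29), with camera adjusted p = 0.0259, and adjusted p = 0.544 with an estimated correlation.

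PF0857 reached 2.24 ± 0.28 and PF0858 0.80 ± 0.17 in the iron list, which did not pass (median -0.02, 0.467). PF1197 fell to -2.03 ± 0.21 and PF0722, an alkyl hydroperoxide reductase subunit, rose to 0.91 ± 0.23 in the oxidative stress list (0.07, 0.887). PF0532 fell to -1.94 ± 0.49 and PF1188, pyruvate kinase, rose to 0.77 ± 0.15, while the acetyl-CoA synthetase and glycolysis lists did not pass (0.305 and 0.719). Heat shock and stress had a median of -0.14, a mean of 0.01 and a test pointing down (0.954), and ferredoxin PF1909 had -0.55 ± 0.19 (adjusted p = 0.0916). Median, mean and test also differed in sign for iron (-0.02, 0.31, up), oxidative stress (0.07, -0.03, up), glycolysis (0.06, -0.03, up) and archaeal ATP synthase (-0.04, -0.0038, up, camera adjusted p = 0.954). The count of 359 was 142 without the 60 min arrays of culture 1, where the archaellum and transposase lists lost their call (adjusted p = 0.074 and 0.108), and 127 without those of culture 2, where archaellum and methionine synthesis did (0.0618 and 0.093). Calls lost with another normalization, background or spot filter setting or in the authors' deposited table were those of the lists 2-oxoacid ferredoxin oxidoreductases, aminoacyl-tRNA synthetases, archaellum and flagellum, methionine synthesis and transposases, and of PF0532, PF0722, PF0858, PF0967 and PF1740, and those lost only with a random block or a sample dye term over 18 arrays were PF1188, PF1453, PF1741 and PF1824.

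The comparison of 60 min with 10 min asked whether the late response differed from the early one, and in it the 0 min RNA and its dye cancel. The branched-chain and histidine lists tested higher at 60 min than at 10 min, and the hydrogenase, mbx and maltose lists tested lower, with 0 to 3 genes called in each. All of them lost the call, at adjusted p = 0.231 to 0.485 with an estimated correlation. Without pairing 8 genes passed by limma, 4 higher and 4 lower, of 258 with an unadjusted p under 0.05. With culture as a block, which suits these paired times, 91 passed, 31 higher and 60 lower. The called genes were PF2026 at 3.51 ± 0.29 (11.4-fold, adjusted p = 0.0188), the leucine pathway genes PF0941 at 1.96 ± 0.25, PF0938 at 1.90 ± 0.24 and PF0939 at 1.71 ± 0.22, and, lower, PF1532, annotated as an NADH oxidase, at -2.54 ± 0.27, PF1341, annotated as an aminomethyltransferase, at -2.28 ± 0.22, PF1196 at -2.01 ± 0.26 and PF1435 (mbh13) at -1.91 ± 0.25. The authors' deposited table gave 4 passing genes, 25% of them higher against 50% here. With a sample dye term over 18 arrays 15 passed, 20% of them higher.

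Among the lists, branched-chain synthesis had 3 higher and 6 not called of 9 genes, 8 higher adjusted over the list alone, 6 higher with culture as a block (median 1.84), with camera adjusted p = 1.3e-12, and adjusted p = 0.231 with an estimated correlation. Histidine synthesis had 0 of 9 genes called by limma, 9 at an unadjusted p under 0.05, 9 higher adjusted over the list alone, 6 higher with culture as a block (median 1.31), with camera adjusted p = 2.2e-11, and adjusted p = 0.244 with an estimated correlation. The sulfur list had 1 higher and 4 not called of 5 genes, 2 higher adjusted over the list alone, 2 higher with culture as a block (median 0.37), with camera adjusted p = 0.0012, and adjusted p = 0.244 with an estimated correlation. The archaellum list (median 0.33) had 0 of 7 genes called by limma, 0 at an unadjusted p under 0.05, 0 adjusted over the list alone, with camera adjusted p = 0.0255, and adjusted p = 0.277 with an estimated correlation. The membrane-bound hydrogenase tested lower (median -1.08), with 1 lower and 13 not called of 14 genes, 12 lower adjusted over the list alone, 2 lower with culture as a block, camera adjusted p = 1.25e-11, and adjusted p = 0.231 with an estimated correlation. The mbx cluster tested lower (median -1.14), with 0 of 13 genes called by limma, 9 at an unadjusted p under 0.05, 9 lower adjusted over the list alone, 7 lower with culture as a block, camera adjusted p = 3.35e-07, and adjusted p = 0.244 with an estimated correlation. Maltose uptake and use tested lower (median -1.001, and -0.42 without culture 1 at 60 min), with 0 of 13 genes called by limma, 6 at an unadjusted p under 0.05, 1 lower adjusted over the list alone, 2 lower with culture as a block, camera adjusted p = 7.51e-06, and adjusted p = 0.35 with an estimated correlation. Hydrogenase I tested lower (median -1.76, and -2.48 without culture 1 and -1.04 without culture 2 at 60 min), with 0 of 4 genes called by limma, 2 at an unadjusted p under 0.05, 0 adjusted over the list alone, 2 lower with culture as a block, camera adjusted p = 0.0211, and adjusted p = 0.485 with an estimated correlation. Hydrogenase II tested lower (median -0.68), with 0 of 4 genes called by limma, 0 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.0187, and adjusted p = 0.409 with an estimated correlation. The 2-oxoacid oxidoreductases tested lower (median -0.82, with 0.15 in culture 1 and -1.33 in culture 2), with 0 of 16 genes called by limma, 6 at an unadjusted p under 0.05, 3 lower adjusted over the list alone, 2 lower with culture as a block, camera adjusted p = 0.000471, and adjusted p = 0.409 with an estimated correlation. Ribosomal proteins (median 0.02, 0.508) and the aromatic list (median 0.59, 0.0762, and 0.0404 with culture as a block) did not pass, nor did iron uptake and storage, with median -0.05, mean 0.43 and a test pointing up (0.113). With 1 culture left out, some lists passed. These were ribosomal proteins without culture 1 at 10 min (0.0258), the aromatic list without culture 2 at 10 min (0.0356) or culture 1 at 60 min (median 1.30, 3.44e-05), and iron without culture 2 at 60 min (0.0321). Others were ferredoxin NADP oxidoreductases without culture 1 at 10 min (0.0313), oxidative stress without either culture at 20 min (0.0427), and glutamate metabolism without culture 1 or 2 at 30 min (0.0339 and 0.0344). Tryptophan synthesis (median -0.55, 0.356) passed as higher without culture 1 at 60 min and as lower without culture 2 (0.000131 and 2e-09).

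All 4 times of culture 1 were hybridized together on 1 day, with 1 array each at 10 and 60 min. These carried different sample dyes, Alexa 488 at 10 min and 594 at 60 min. Within that day the median of 60 min minus 10 min was 1.79 for branched-chain synthesis, 1.87 for histidine synthesis, 0.74 for the sulfur list, 0.09 for the archaellum list, -1.74 for the membrane-bound hydrogenase, -1.99 for hydrogenase I, -0.54 for hydrogenase II, -1.30 for mbx, -1.39 for maltose uptake and use, and 0.11 for the 2-oxoacid oxidoreductases, whose sign it turned. That day's 60 min array, array b of culture 1, was the one that stood apart for histidine, at 2.73 against 1.40 to 1.56. The limma count of 8 was 0 without culture 1 at 10 min, without culture 1 at 60 min and without culture 2 at 60 min (191, 195 and 233 genes at an unadjusted p under 0.05), 1 without culture 2 at 10 min, and 4 without either culture at 20 min. Without 1 array it was 14 without array b of culture 1 at 10 min, 13 without array a of culture 1 at 60 min, 5 without array a of culture 2 at 20 min, 4 without array b of culture 2 at 20 min, 3 without array a of culture 1 at 10 min, array b of culture 1 at 20 min, array b of culture 1 at 30 min, array a of culture 2 at 30 min or array b of culture 2 at 60 min and 1 without array b of culture 1 at 60 min. The lists that lost their call when 1 culture was left out at 10 or 60 min were hydrogenase I and II, the archaellum list and the 2-oxoacid oxidoreductases (medians -1.04, -0.65, 0.30 and -0.06 without culture 2 at 60 min).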

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

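Of the tests reported here, those of the reference dye in the ribosomal proteins and of shared slides in branched-chain synthesis were chosen only after the result was seen, as was leaving out the arrays of conflicting dye labels.

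Some arrays stood far from the others of their time. Chance alone marks about 1 in 20 groups in this way, which gives 6.4 of the 128 groups examined, and 7 were found. The branched-chain median was 1.04 on array b of culture 2 at 20 min, against 2.27 to 2.32 on the other arrays of that time. Heat shock and stress had a median of 0.12 on array a of culture 2 at 10 min, against -0.29 to -0.26, and of 0.56 on array a of culture 2 at 30 min, against -0.44 to -0.18. The histidine median was 2.73 on array b of culture 1 at 60 min, against 1.40 to 1.56, and hydrogenase maturation had -0.79 on array b of culture 2 at 10 min, against -0.28 to -0.20. Methionine synthesis had 1.40 on array a of culture 1 at 30 min, against 0.81 to 1.03. The median background of the 0 min channel was 174 scanner units on array a of culture 1 at 20 min, against 472 to 492.

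Other results differed between 60 min and 10 min. The lists that tested lower at 60 min were hydrogenase I (median difference -1.76), mbx (-1.14), membrane-bound hydrogenase (-1.08), maltose uptake and use (-1.001), 2-oxoacid ferredoxin oxidoreductases (-0.82) and hydrogenase II (-0.68). Those that tested higher were branched-chain synthesis (1.84), histidine synthesis (1.31), the sulfur response genes (0.37) and archaellum (0.33). None of these 10 passed camera with an estimated correlation (adjusted p = 0.231 to 0.485), and the 2-oxoacid list had 0.15 in culture 1, -1.33 in culture 2 and 0.11 within 1 hybridization day. The genes were PF2026 (3.51), PF0941 (1.96), PF0938 (1.90), PF0939 (1.71), PF1435 (-1.91), PF1196 (-2.01), PF1341 (-2.28) and PF1532 (-2.54). In 2 lists every array at 1 time lay on the other side of 0 from every array at another. The ferredoxin NADP oxidoreductases were above 0 at 10 min and below it at 20 and 30 min, with differences of -1.43 and -1.77, and oxidative stress was above 0 at 10 min and below it at 20 min, with a difference of -1.03. These opposite directions were not tested.

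The branched-chain list tested higher at 60 min than at 10 min (median 1.84, 3 of 9 genes called), with camera adjusted p = 1.3e-12, and adjusted p = 0.231 with an estimated correlation. Different sample dyes at those times are argued against as the whole cause, since with sample dye as a term the median was 1.75 and the lowest member 0.95, or 1.80 and 0.39 without 2 arrays on 1 slide whose dye labels conflict. Noise of a slide or its reference channel is argued against for the rise between 10 and 30 min, where 3 slides held a sample of each time: the median of 30 min minus 10 min was 1.19 on the lowest and 2.18 and 2.01 on the others (SD 0.53). Time after sulfur and growth of the culture over the same hour stay open, and no sample without sulfur was analysed here.

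The ribosomal protein list tested higher than 0 min at every time (medians 0.59 to 0.99, with 5, 17, 47 and 20 of 66 genes called), and it did not pass with an estimated correlation (adjusted p = 0.297 to 0.387). Spot brightness is argued against, because at each time the median lay at percentile 100 of 10000 random lists matched on intensity. A fixed bias of the reference dye as the whole cause is argued against by the mean of 0.498 for 30 min minus 10 min in 3 pairs of arrays labelled with the same culture and dye (0.30, 0.58 and 0.61, SD 0.17). The last pair appears to share a slide, so 1 of its dye labels may be wrong, and without it the mean was 0.441 (SD 0.20); a partial bias at the level of 10 min stays open. The median of 60 min minus 10 min was 0.02, and a response to sulfur and the time of growth could both apply and were not separated.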

How the results depend on the processing

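Of the alternatives reported here, leaving out the arrays of conflicting dye labels and leaving out genes near background were chosen only after seeing the data. The counts of called genes were 80, 422, 484 and 359 at 10, 20, 30 and 60 min against 0 min and 8 for 60 min against 10 min, and 67 of 135 list tests passed. Median centring, print-tip loess, no background correction, an offset of 16, leaving out the dimmest genes, keeping excluded spots and the added alternatives each gave counts within 1.5 times of these. No called value of a named gene turned its direction under any alternative. Signal over background limits dim genes: 25, 15, 5 and 31 genes at 10, 20, 30 and 60 min were under 2 times the background in the sample channel on every array of that time, and 1 of them was called. That gene, PF0926 at 60 min, chosen after its value was seen, has only a bound and was at least 11.4-fold lower.

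With culture as a block 225, 800, 853 and 690 genes passed against 0 min and 91 for 60 min against 10 min. Every gene called without the block was also called with it. The block uses the pairing in 60 min against 10 min. Against 0 min its calls do not measure agreement between the cultures. The block ended the glycolysis call at 10 min and brought in archaeal ATP synthase at 30 min (medians -0.16 in culture 1 and 1.01 in culture 2), hydrogenase maturation at 30 min and at 60 min (0.03 and -0.60), the aromatic list in 60 min against 10 min, and PF0894 at all 4 times. It changed no other call of a list or named gene. Its simulated share of false calls was higher against 0 min.

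With all 18 arrays and culture and time as a random block 136, 772 and 548 genes passed at 10, 30 and 60 min and 39 for 60 min against 10 min. With hybridization day in its place the counts were 437, 929, 1164, 865 and 244, and with slide 523, 943, 1231, 905 and 244. The estimated correlation within blocks was 0.379 for culture and time, 0.416 for day and 0.552 for slide. Day and slide leave repeat arrays of a culture on other days or slides as independent values, by construction. A sample dye term gave 15 genes for 60 min against 10 min, 20% of them higher, and the deposited value table gave 4, and the cause was not tested. In that table the median of all genes lay at -0.11 at 30 min and -0.15 for 60 min against 10 min. A log2 ratio of at least 1 left 225, 280 and 227 genes at 20, 30 and 60 min, by its construction. Without the empirical Bayes step, which leaves fewer degrees of freedom, 52, 169, 230, 196 and 1 passed. With an estimated correlation in camera 0 of 135 list tests passed, and with fry 56 passed.

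Leaving out 1 culture at 1 time gave 27 to 83 genes at 10 min, 122 to 353 at 20 min, 85 to 493 at 30 min, 127 to 365 at 60 min and 0 to 9 for 60 min against 10 min, where 8 genes had passed. The time that lost a culture then rests on 1 culture, assumed to vary like the other times. Leaving out 1 array gave 59 to 110, 312 to 492, 401 to 528, 307 to 406 and 1 to 14. The 60 min against 10 min count of 14 came without array b of culture 1 at 10 min and that of 1 without array b of culture 1 at 60 min. List tests passed 62 to 72 times without 1 culture and 65 to 69 times without 1 array. Among 2152 values of named genes without 1 culture 478 lost their call, and among 4842 without 1 array 244 did. Of 269 values of named genes 18 lost it with median centring, 17 with print-tip loess, 20 without background correction, 3 with excluded spots kept, 31 in the deposited table, 22 with the dye term, 10 with culture and time as a random block, 32 without the arrays of conflicting dye labels, 35 with a log2 ratio of at least 1 and 122 without the empirical Bayes step. Without those arrays the counts were 59, 375, 366, 315 and 8.

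Against 0 min, the lists that lost their call at 10 min were glycolysis without 10 min culture 2 (0.123) and 60 min culture 2 (0.0508) and hydrogenase maturation without 10 min culture 2 (0.0714). At 20 min it was RNA polymerase subunits without 20 min culture 2 (0.53). At 30 min it was archaellum without 30 min culture 1 (0.0843). At 60 min these were 2-oxoacid oxidoreductases without 10 min culture 1 (0.0527) and 10 min culture 2 (0.0568) and 60 min culture 2 (0.72), archaellum without 60 min culture 1 (0.074) and 60 min culture 2 (0.0618), methionine synthesis without 60 min culture 2 (0.093) and transposases without 60 min culture 1 (0.108). In 60 min against 10 min these were 2-oxoacid oxidoreductases without 10 min culture 2 (0.117) and 60 min culture 2 (0.262), archaellum without 10 min culture 2 (0.174) and 60 min culture 1 (0.0636) and 60 min culture 2 (0.0734), hydrogenase I without 10 min culture 1 (0.121) and 60 min culture 2 (0.314) and hydrogenase II without 10 min culture 2 (0.115) and 60 min culture 2 (0.0571). Values in brackets are adjusted p. In all, 21 list calls were lost and 27 gained among 1080 list tests without 1 culture, and 8 and 18 among 2430 without 1 array. Of 135 list tests 6 lost their call with median centring, 2 with print-tip loess, 4 without background correction, 7 in the deposited table, 3 with the dye term, 2 with each random block and 18 with fry, and none of those medians changed sign. The tryptophan list at 60 min turned round: the median was 0.60 without culture 1 (adjusted p = 0.0085) and -2.08 without culture 2, and for 60 min against 10 min 0.87 (0.000131) and -2.07. The arginine and lysine list, not called with both cultures, passed as lower without culture 1 at 20 min (median -1.44, adjusted p = 0.0435) and 30 min (-1.68, 0.00144). The cultures differ there, and the cause was not tested beyond dye, a single slide or day, and the 0 min RNA for arginine and lysine.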

Other observations

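The 3 tests of the arginine and lysine difference between cultures and the choice of the gene runs described here were made only after the result was seen.

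Called genes lay side by side in runs of neighbouring locus tags, some outside the lists, some reaching past them and some within them. Lower runs included PF1336 to PF1341, with genes annotated as a cytosine permease, transcriptional activators and an aminomethyltransferase, at a median log2 ratio of -2.11 at 30 min and -2.75 at 60 min over 6 genes. The run of hydrogenase II reached on to PF1333 and PF1334, annotated as thiamine synthesis genes, with PF1334 at -1.47 at 30 min. PF0924 to PF0927, which hold a heme biosynthesis gene, had -2.44 over 4 genes at 30 min. The run PF0971 to PF0975, which starts with a gene of the 2-oxoacid oxidoreductase list and goes on with genes annotated as an acyl carrier protein synthase and an acetyl-CoA synthase, had -3.33 at 60 min over 5 genes. PF1532 to PF1535, with an NADH oxidase, a stomatin homolog and an alpha-glucan phosphorylase, had -1.30 at 20 min, and PF1794 to PF1798, with a sarcosine oxidase subunit and a polyferredoxin, had -1.29 at 60 min.

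Higher runs included PF2029 to PF2032, annotated as a nitrogenase reductase fragment, a ferredoxin-family protein and an iron-sulfur cluster binding protein, at a median of 1.19 at 20 min over 4 genes. Within the ribosomal protein list, PF1805 to PF1815 and PF1818 to PF1825 stood at 1.03 over 11 genes and 1.26 over 8 genes at 30 min. PF1642 to PF1649, all from the RNA polymerase and ribosomal protein lists, had 1.16 over 8 genes at that time. PF1657 to PF1667 reached past the histidine genes at 60 min, with 1.64 over 11 genes. Neighbouring genes in an archaeon are often transcribed together, so these are not independent measurements, and the runs were not tested against chance.

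The arginine and lysine list differed between the cultures at 30 min, with 0.79 in culture 1 and -1.68 in culture 2, a difference of 2.47. Sample dye is argued against, since between the means of the arrays' medians the difference was 2.51 over all dyes, 2.48 within Alexa 488 and 2.50 within Alexa 546. A slide or hybridization day is argued against by the gap of 2.23 between the lowest array of culture 1 and the highest of culture 2. The 0 min RNA of 1 culture, which is on all its arrays, is argued against by the difference between culture medians of 0.13 at 60 min, after 0.36 at 10 min and 1.77 at 20 min. A difference of state between the cultures that comes and goes may apply, as a hypothesis with 2 cultures and no further replicate.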
